A study of Homo sapiens with 9 samples.

How the data were processed

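Total RNA of MDA-MB-231 cells, reverse transfected in 6-well plates with AllStar, Qmimic or Dmimic at 10 nM, was taken 48 h later from 3 biological replicates per group and hybridised to 9 Affymetrix HG-U133 Plus 2.0 arrays, 1 per well. The deposited values are log2 signals per probe set, which the authors made with RMA (background correction, quantile normalisation and summary of the probes of a probe set). The series text names AFFYGUI and limma for their work, and the submitters' processing notes name RMA and limma without versions. The table held 54675 probe sets for the 9 arrays, with no missing replicate and no identical pair of arrays. The values run as log2 RMA values do, and 8 arrays had nearly equal distributions, while AllStar replicate 3 had a narrower one. Arrays give no depth, and their number limits the precision.

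The 62 control probe sets were set aside for quality checks and the other 54613 were tested without a filter on low values. The annotation given with the series names 1 gene for 41091 of them, several for 1801 and none for 11721, and 0 symbols had to be updated. A gene was represented by its probe set with the highest mean over the 9 arrays, which gave 19775 genes. Quality was judged by correlations between arrays, their interquartile ranges, the hybridisation spikes (9 probe sets), the poly-A spikes added before labelling (12 probe sets) and probe sets for 18S and 28S ribosomal RNA (3 each).

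In limma 3.58.1 under R 4.3.3, 1 linear model with 3 groups was fitted to all 9 arrays, and moderated statistics (eBayes, no trend) were taken for Qmimic versus AllStar, Dmimic versus AllStar, the mean of both mimics versus AllStar and Qmimic versus Dmimic. A probe set was called when its Benjamini-Hochberg adjusted p over the 54613 probe sets was under 0.05 and its change at least 1.5-fold. The series text words its fold threshold as log2 and 1.5-fold together, so a log2 change of at least 1.5 was run as an alternative. All p values named adjusted for a gene come from this limma model. AXL was tested in the same model and with an exact two-sided permutation test of the group means, whose smallest possible p for 3 arrays against 3 is 0.1.

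The samples, tests, thresholds, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each mimic against AllStar, the 10 called genes with the largest rise and the 10 with the largest fall whose mimic arrays all lie beyond all AllStar arrays in the fit, and the 5 and 5 likewise for Qmimic against Dmimic, passing over symbols that start with LOC. It also took AXL, up to 4 members of each list with the smallest adjusted p, and CDK4, CDK6, CCND1, MET, NOTCH1, BCL2, SIRT1 and E2F3 whatever their result. With all 9 arrays the rule named no gene for Qmimic and 2 for Dmimic. It was therefore also applied to the fit without AllStar replicate 3, a choice made after the data were examined, in which the mimic arrays had to lie beyond 2 AllStar arrays. Genes called over both mimics were named by the size of their change and by function, after their values were seen.

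There were 20 lists with 611 symbols, of which 562 were measured: reported miR-34a targets, receptor tyrosine kinases, DNA replication and G1/S, mitosis and G2/M, p53 targets, interferon response, NF-kB and inflammatory cytokines, mesenchymal and invasion genes, epithelial genes, extracellular matrix and collagens, cholesterol and fatty acid synthesis, integrated stress and unfolded protein response, glycolysis and hypoxia, WNT and NOTCH pathway, small RNA machinery, apoptosis regulators, ribosomal proteins, and markers of luminal breast epithelium, leukocytes, and fibroblasts and endothelium. They were written from general knowledge, and AXL was kept out of them. Each was tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the 20 lists of a comparison, and again with an estimated correlation. Members were counted with p adjusted over all probe sets and adjusted over the list alone, with the 1.5-fold threshold in both. A list of 108 cilium genes, of which 98 were measured, was written after cilium genes had been seen among the calls, and left out the genes first noticed, though KIF3A, which was among the calls over both mimics, stayed in it.

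The overlap of the mimics was counted per direction, with the overlap of independent lists. It was also set against lists of the same sizes, taken by moderated t, in 100 simulations of unchanged groups that share the AllStar arrays, a comparison added after the data were examined. The correlation of their fold changes was set against 100 simulations of unchanged groups that share the AllStar arrays. The replicate numbers did not pair arrays across groups: of 9 same-number pairs, 3 had a residual correlation above 0.1, over a range of -0.275 to 0.219.

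The alternatives were a block for the replicate number, the stricter fold threshold, adjusted p alone, the upper part of the probe sets by mean level (at or above the median of 5.49), centring of each array, repeated quantile normalisation, cyclic loess, eBayes with a trend, only the arrays of the groups compared, the mean of all probe sets of a gene, and leaving out each array in turn. Array weights, the other AXL probe set, and the fit without AllStar replicate 3 as a base for the other alternatives were added after the data were examined. The planned search for miR-34a seed sites was not run, since the reference at hand holds no 3' UTR sequences.

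The model was tested on simulated data with 54613 probe sets, of which 67, 67 and 66 per mimic were changed 1.5-, 2- and 3-fold, with noise like that of AllStar replicate 3 on 1 array. From all 9 arrays it recovered 20.9% of the 1.5-fold, 74.6% of the 2-fold and 98.5% of the 3-fold changes for Qmimic, and called 0 unchanged probe sets. Without that array it recovered 31.3%, 97.0% and 100%. For Dmimic the values were 17.9%, 76.1% and 98.5%, with 1 unchanged probe set called. Without that array they were 43.3%, 97.0% and 98.5%, with 1 unchanged probe set called. This simulation drew probe sets independently and shuffled the deviation of AllStar replicate 3 among probe sets of like level. Its rates therefore do not give the power of the real comparison. There 0 probe sets were called for Qmimic from all 9 arrays, although DYNC2LI1 (log2 change 1.59) and OSCP1 (1.53) lay above 2-fold. In a simulation of lists over 19775 genes, a list shifted by -0.3 had a camera adjusted p of 1.49e-54, or 0.000128 with an estimated correlation, and the preset correlation also called 1 of 19 unchanged lists. That simulation drew genes independently and without the noise of AllStar replicate 3. It does not show what the test with an estimated correlation could detect in lists whose members move together.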

Results

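The data were gene expression profiles of MDA-MB-231, a cell line from a triple-negative breast cancer, 48 h after transfection with a small RNA at 10 nM. There were 3 groups of 3 biological replicates, given AllStar (a negative control), Qmimic or Dmimic, and the series title names the microRNA miR-34a and the receptor tyrosine kinase AXL. The labels do not say what the letters Q and D stand for, and they give no sequence for either mimic. Each of the 9 wells was measured on 1 HG-U133 Plus 2.0 array, and the 54613 probe sets that are not controls were tested. The number of arrays limits the precision: the median 95% half-width of a fold change against AllStar was 0.26 on the log2 scale.

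AllStar replicate 3 stood apart from the other 8 arrays. Its correlation with them across probe sets was 0.974 to 0.981, against 0.993 to 0.998 among the other 8. Its probe sets for 18S ribosomal RNA had a mean log2 value of 8.73, against 5.27 to 6.26 on the other arrays, and those for 28S ribosomal RNA 9.51, against 7.29 to 8.34. Spikes added at hybridisation were high on it (10.12, against 9.23 to 9.78), while spikes added before labelling were low (5.83, against 6.16 to 6.63). The range of its values was narrow, with an interquartile range of 2.99 against 3.41 to 3.53. Relative to the mean of AllStar replicates 1 and 2, probe sets at a log2 level of 4 to 6 lay at a median of 0.21 and those at 8 to 10 at a median of -0.45. The labels give no reason to leave the array out, so values from all 9 arrays are the primary ones. Leaving out each array in turn was planned, but the fit without AllStar replicate 3 was singled out after its values were seen, and its results stand beside the primary ones.

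**Figure D1:**
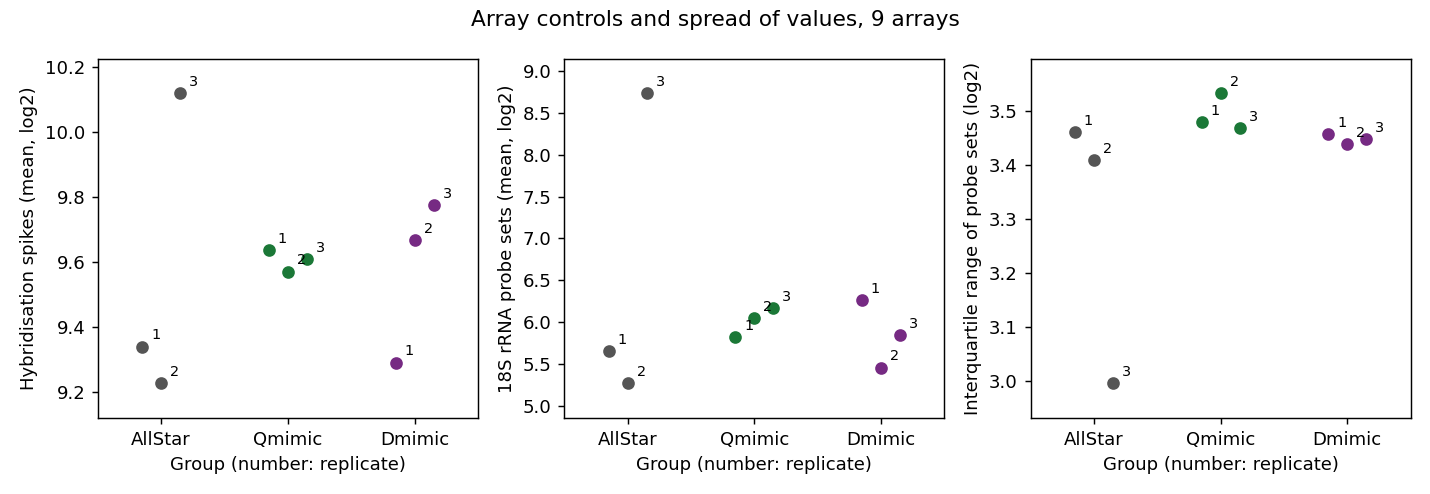
Mean log2 value of the hybridisation spikes, mean log2 value of the 18S ribosomal RNA probe sets and interquartile range of all probe sets, 1 point per array, for the AllStar, Qmimic and Dmimic groups. AllStar replicate 3 lies at 10.12, 8.73 and 2.99, outside the range of the other 8 arrays in each panel.

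The comparison of Qmimic with AllStar asks which transcripts the first mimic changes. No probe set passed the thresholds with all 9 arrays, while 8924 had an unadjusted limma p under 0.05, where 2730.65 would be expected by chance, and the smallest adjusted p was 0.111. Repeated quantile normalisation of all 9 arrays gave 27 higher and 36 lower, and cyclic loess 69 higher and 60 lower. In the fit without AllStar replicate 3, 295 probe sets passed, 163 higher and 132 lower with Qmimic. In that fit the named genes with the highest rises were OSCP1 (2.79-fold, adjusted p = 0.0324) and DYNC2LI1 (2.49-fold, adjusted p = 0.0217), the latter a subunit of the dynein that moves cargo along cilia. PAPPA, a protease that cleaves an IGF-binding protein, was 2.19-fold higher (adjusted p = 0.00482) and the chromatin protein HMGA2 2.28-fold higher (adjusted p = 0.00981, on 1 of its 9 probe sets). The named gene with the deepest fall was SGPP1, which removes the phosphate from sphingosine-1-phosphate, at 2.38-fold (adjusted p = 0.00482), and FOSL1, a subunit of the transcription factor AP-1, was 2.20-fold lower (adjusted p = 0.0109).

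Further genes higher with Qmimic without AllStar replicate 3 were GDPD1 (2.31-fold), the junction protein PLEKHA7 (2.30-fold) and the cilium-linked genes DNAAF4 (2.08-fold) and LZTFL1 (2.04-fold). The hedgehog-binding protein HHIP (2.02-fold) and ANKRD46 (1.95-fold) were higher as well. Lower were the pentose phosphate enzyme RPIA (2.11-fold), the deadenylase CNOT6 (2.02-fold), LPGAT1 (1.99-fold), PLEKHA1 (1.98-fold), the general transcription factor subunit TAF5 (1.98-fold), the protein kinase A inhibitor PKIA (1.97-fold), ARHGAP19 (1.87-fold) and NCBP2AS2 (1.86-fold). The adjusted p of these 20 genes ranged from 0.111 to 0.304 with all 9 arrays, and all 295 probe sets had the same sign there. As the fit of all 9 arrays holds every array of the other fit, the shared sign is no separate support. Some of these genes passed with Qmimic on a part of their probe sets. HHIP passed on 1 of 4, GDPD1 and LPGAT1 on 1 of 3, TAF5 and PKIA on 1 of 2 and PAPPA on 4 of 11. DYNC2LI1 and LZTFL1 passed on 2 of 4 and ARHGAP19 on 2 of 3. SGPP1, PLEKHA7, CNOT6 and PLEKHA1 passed on 2 of 2. After a scaling of each array to its median the split without AllStar replicate 3 was 234 higher and 118 lower. The count of 295 also rested on the remaining controls: it was 2 without AllStar replicate 1 as well and 9 without AllStar replicate 2, and it was 89 without Qmimic replicate 1, 90 without Qmimic replicate 2 and 486 without Dmimic replicate 3.

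The comparison of Dmimic with AllStar asks the same of the second mimic. With all 9 arrays EDN1, which encodes the vasoconstrictor peptide endothelin-1, rose 2.34-fold with Dmimic, from a log2 level of 9.0 ± 0.14 to 10.23 ± 0.09 (SD, n = 3; adjusted p = 0.00768 from limma). A second EDN1 probe set rose 2.14-fold (adjusted p = 0.0167), and PDE1C, a calcium-dependent phosphodiesterase, rose 2.18-fold on 1 of its 6 probe sets, from 8.68 ± 0.23 to 9.80 ± 0.08 (SD, n = 3; adjusted p = 0.0473 from limma). These 3 probe sets were the only ones that passed, and 7004 had an unadjusted p under 0.05. All 3 passed in the fit without AllStar replicate 3 too, where 472 probe sets did, 235 higher and 237 lower.

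In the fit without AllStar replicate 3, OSCP1 (3.64-fold, adjusted p = 0.0155), HHIP (3.23-fold, adjusted p = 0.0103) and DYNC2LI1 (2.92-fold, adjusted p = 0.0138) were the named genes that rose most with Dmimic. They were followed by DNAAF4 (2.55-fold), FANK1 (2.47-fold), SPATA17 (2.31-fold), PLEKHA7 (2.28-fold), PAPPA (2.28-fold), DPCD (2.22-fold) and EDN1 (2.22-fold). The log2 level with AllStar replicates 1 and 2 was low for SPATA17 (3.88) and FANK1 (4.86). SPATA17 and PLEKHA7 passed on 1 of 2 probe sets, DYNC2LI1 on 2 of 4, EDN1 on 2 of 3 and PAPPA on 5 of 11. HHIP passed on 4 of 4 and DPCD on 2 of 2. The named genes with the deepest falls were PKIA (2.57-fold, adjusted p = 0.0132), TPD52 (2.47-fold) and CCNE2 (2.38-fold), the last of which encodes cyclin E2 of the entry into S phase. The replication factors MCM10 (2.25-fold) and GINS3 (2.21-fold) fell as well, as did TAF5 (2.33-fold), LEF1, a transcription factor of the WNT pathway (2.32-fold, adjusted p = 0.0195), GCH1 (2.23-fold), FAM111B (2.20-fold) and FOSL1 (2.17-fold, adjusted p = 0.0127). Apart from EDN1, these genes had an adjusted p of 0.0669 to 0.241 with all 9 arrays, and all 472 probe sets had the same sign there. The shared sign is again no separate support, as the fits share their arrays.

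The count of 3 for Dmimic with all 9 arrays was 0 without AllStar replicate 1, without Qmimic replicate 1, 2 or 3 or without Dmimic replicate 1 or 3, and 6 without AllStar replicate 2. Repeated quantile normalisation gave 58 higher and 45 lower, and cyclic loess 142 higher and 92 lower, where the deposited values gave 3 higher and 0 lower. The count of 472 without AllStar replicate 3 was 1 without AllStar replicate 1 as well, 15 without AllStar replicate 2, 240 without Qmimic replicate 2, 902 without Dmimic replicate 2 and 295 without Dmimic replicate 3. It was 13 when the AllStar and Dmimic arrays alone were fitted.

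Taking the mean of both mimics against AllStar asks what the mimics change in common, with 6 arrays against 3. With all 9 arrays 40 probe sets rose and 4 fell, which named 26 genes and 4 genes. DYNC2LI1 rose 4.27-fold (SE 0.29 log2, adjusted p = 0.0431) and 3.27-fold (SE 0.23 log2, adjusted p = 0.042) on 2 probe sets, OSCP1 3.30-fold (SE 0.22 log2, adjusted p = 0.0401), HHIP 2.99-fold and PAPPA 2.74-fold, 2.61-fold and 1.80-fold on 3 probe sets. The mRNA decapping enzyme DCP2 rose 2.11-fold and 2.02-fold on 2 probe sets, and the receptor tyrosine kinase ERBB3 1.96-fold and 1.79-fold. HMGA2 rose 2.33-fold, LEPROT 2.79-fold, and the cilium genes KIF3A and CLUAP1 1.91-fold and 1.72-fold. FOSL1 fell 2.06-fold (adjusted p = 0.0401), the NADPH oxidase NOX5 1.74-fold (adjusted p = 0.042), MET 1.68-fold on 1 of its 4 probe sets (adjusted p = 0.042) and ULBP2, a ligand of the lymphocyte receptor NKG2D, 1.64-fold (adjusted p = 0.043).

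The largest rise over both mimics, 4.40-fold, was on a probe set that the annotation does not name. The thresholds passed 44 probe sets, and 10467 had an unadjusted p under 0.05. The count was 394 without AllStar replicate 3 (208 higher, 186 lower), and 42 of the 44 passed in both fits. The count of 44 with all 9 arrays was 14 without AllStar replicate 2 and 0 without AllStar replicate 1 or without any 1 of the 6 mimic arrays, and 0 after each array was centred on its median. The split was 162 higher and 82 lower after repeated quantile normalisation and 242 higher and 132 lower after cyclic loess. The count of 394 without AllStar replicate 3 was 0 without AllStar replicate 1 as well, 17 without AllStar replicate 2, 207 without Qmimic replicate 1, 191 without Qmimic replicate 2 and 631 without Dmimic replicate 2.

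AXL, the receptor tyrosine kinase in the series title, lay lower in each of the 6 mimic arrays than in each of the 3 AllStar arrays on both of its probe sets. On the probe set with the higher level the log2 level was 12.45 ± 0.27 with AllStar, 11.74 ± 0.17 with Qmimic and 11.72 ± 0.15 with Dmimic (SD, n = 3 each). The log2 differences from AllStar were -0.71 (SE 0.15, adjusted p = 0.162) and -0.73 (SE 0.15, adjusted p = 0.115), sizes of 1.64-fold and 1.66-fold that did not pass the adjustment. On the other probe set the levels were 8.95 ± 0.10, 8.16 ± 0.30 and 8.02 ± 0.44, with differences of -0.79 (adjusted p = 0.193) and -0.93 (adjusted p = 0.136). An exact two-sided permutation test gave p = 0.1 for each mimic and each probe set, the smallest p that 3 arrays against 3 allow. The mimics differed from each other by 0.02 on the higher probe set, with a 95% half-width of 0.33 (exact permutation p = 0.8), and by 0.14 on the other (exact permutation p = 0.7).

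Without AllStar replicate 3, the array with the highest AXL value on the higher probe set, the differences there were -0.55 (adjusted p = 0.0394) with Qmimic and -0.57 (adjusted p = 0.0317) with Dmimic. The adjusted p of AXL then passed, and its size lay under 1.5-fold. On the other probe set the differences were -0.85 (adjusted p = 0.0847) and -0.99 (adjusted p = 0.0511). For the mean of both mimics they were -0.72 (adjusted p = 0.0605) on the higher and -0.86 (adjusted p = 0.0841) on the other probe set with all 9 arrays. In the fit without AllStar replicate 3 they were -0.56 (adjusted p = 0.0215, under 1.5-fold) and -0.92 (1.89-fold, adjusted p = 0.0404), and the latter passed both thresholds. The title names AXL from this work, so these values are no independent evidence on AXL.

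**Figure D2:**
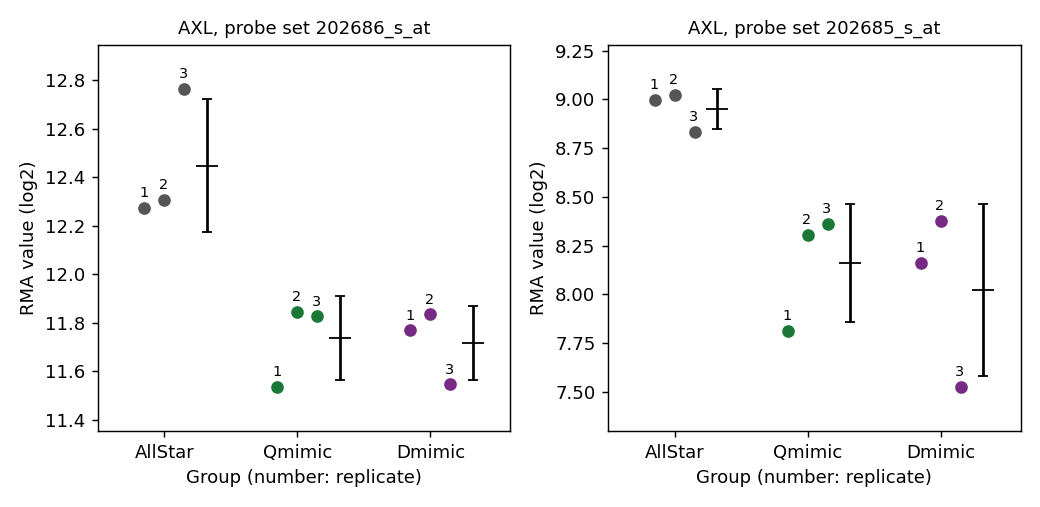
RMA values (log2) of AXL on its 2 probe sets, 1 point per array, in the AllStar, Qmimic and Dmimic groups, with the mean and SD of each group beside its points (n = 3). On the probe set with the higher level the group means are 12.45, 11.74 and 11.72, and every mimic array lies below every AllStar array on both probe sets.

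Reported targets of miR-34a, a list of 45 measured genes from which AXL was kept out, were lower as a group with both mimics. The median log2 change with all 9 arrays was -0.17 with Qmimic (33 of 45 genes negative, camera adjusted p = 0.000981) and -0.24 with Dmimic (35 of 45 negative, camera adjusted p = 1.01e-07). With an estimated correlation between genes, neither call held (adjusted p = 0.643 and adjusted p = 0.596). AllStar replicate 3 itself lay at a median of -0.26 on this list relative to AllStar replicates 1 and 2. Random lists of like level lay at -0.30 there, so a part of array quality in the list values is not excluded. Over all probe sets limma called 0 members for either mimic with all 9 arrays, and the counts adjusted over the list alone were 2 higher and 5 lower with Qmimic and 2 higher and 10 lower with Dmimic. The medians without AllStar replicate 3 were -0.24 and -0.34, with an adjusted p = 0.597 and adjusted p = 0.547 when the correlation was estimated. In that fit 1 member rose and 6 fell with Qmimic (1 and 10 adjusted over the list alone), and 1 rose and 16 fell with Dmimic (1 and 16 adjusted over the list alone). The member that rose was HMGA2, and 6 members passed in the same direction with both mimics.

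Among the targets that fell without AllStar replicate 3 were the small GTPase RRAS (1.71-fold with Qmimic, adjusted p = 0.0144; 1.94-fold with Dmimic, adjusted p = 0.0083) and ULBP2 (1.61-fold, adjusted p = 0.0168; 1.84-fold, adjusted p = 0.00837). CSF1R (1.51-fold, adjusted p = 0.0155) and E2F5 (1.76-fold, adjusted p = 0.0451) fell with Qmimic, and LGR4 (1.76-fold, adjusted p = 0.0175) and LEF1 with Dmimic. The G1 kinase CDK6 differed by -0.53 with Qmimic (adjusted p = 0.0128, under 1.5-fold) and by -0.73 with Dmimic (adjusted p = 0.00493). A second CDK6 probe set differed by -0.76 with Dmimic (adjusted p = 0.0081), while the others had an adjusted p of 0.0512 to 0.913 with Dmimic. CDK4 differed by -0.54 with Qmimic (adjusted p = 0.137) and by -0.88 with Dmimic (adjusted p = 0.0342). MET differed by -0.51 (adjusted p = 0.095) and -0.83 (adjusted p = 0.0219) on its highest probe set, while 2 of its other 3 probe sets fell 1.80-fold (adjusted p = 0.0144) and 1.73-fold (adjusted p = 0.0143) with Qmimic and 2.06-fold (adjusted p = 0.0083) and 1.70-fold (adjusted p = 0.0158) with Dmimic. The deacetylase SIRT1 differed by -0.26 (adjusted p = 0.329) and -0.70 (adjusted p = 0.0308). Sizes under 1.5-fold were measured for CCND1 (-0.41, adjusted p = 0.0308; -0.28, adjusted p = 0.0855), NOTCH1 (-0.36, adjusted p = 0.0696; -0.44, adjusted p = 0.0348) and E2F3 (-0.33, adjusted p = 0.141; -0.52, adjusted p = 0.0393). The second CCND1 probe set lay at -0.25 with Qmimic (adjusted p = 0.361) and -0.36 with Dmimic (adjusted p = 0.193). The second NOTCH1 probe set lay at -0.05 (adjusted p = 0.86) and -0.04 (adjusted p = 0.908), and that of E2F3 at -0.33 (adjusted p = 0.0811) and -0.40 (adjusted p = 0.0432). BCL2 lay at 0.01 (adjusted p = 0.954) and -0.00 (adjusted p = 0.991) on its highest probe set. Its other probe sets differed by -0.91 (adjusted p = 0.0268), -0.19 (adjusted p = 0.314) and -0.02 (adjusted p = 0.937) with Dmimic. None of these 8 fixed genes passed on its representative probe set for either mimic with all 9 arrays.

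Genes of DNA replication and the G1/S transition had negative values with both mimics for all 38 measured members with all 9 arrays, a call that held at the preset correlation and not at an estimated one. The median log2 change was -0.36 with Qmimic (camera adjusted p = 4.02e-11) and -0.51 with Dmimic (camera adjusted p = 1.01e-20). All 38 measured genes of mitosis and G2/M were negative too, with medians of -0.31 (camera adjusted p = 2.17e-05) and -0.44 (camera adjusted p = 4.12e-12). The members of both lists move closely together, and with an estimated correlation the adjusted p = 0.643 with Qmimic and adjusted p = 0.596 with Dmimic for both lists. Limma called 0 members of either list over all probe sets with all 9 arrays. Adjusted over the list alone, 2 replication genes fell with Qmimic and 12 with Dmimic, and 0 mitosis genes with either. Leaving out AllStar replicate 3 gave medians of -0.50 and -0.62 for replication (estimated correlation: adjusted p = 0.597 and adjusted p = 0.609) and -0.43 and -0.55 for mitosis (adjusted p = 0.629 and adjusted p = 0.609).

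AllStar replicate 3 itself lay at a median of -0.35 on the replication list relative to AllStar replicates 1 and 2, where random lists of like level lay at -0.36. The hybridisation spikes of the mimic arrays were on average 0.308 above those of AllStar replicates 1 and 2, on the side of AllStar replicate 3. Dmimic replicate 1 (9.29) lay between AllStar replicate 2 (9.23) and AllStar replicate 1 (9.34). A part of array quality in the list values is therefore not excluded. Without AllStar replicate 3, 2 replication genes fell with Qmimic and 9 with Dmimic over all probe sets, and 11 and 23 adjusted over the list alone. The helicase subunits MCM3 and MCM2 fell 2.09-fold (adjusted p = 0.0268) and 2.06-fold (adjusted p = 0.0274) with Dmimic, and the licensing factor CDC6 1.70-fold (adjusted p = 0.0274). With Qmimic E2F2 fell 1.53-fold (adjusted p = 0.024) and CDC6 1.58-fold (adjusted p = 0.0481). Of the mitosis genes 0 passed over all probe sets with either mimic, and adjusted over the list alone 0 passed with Qmimic and 14 with Dmimic. Cyclin A2, CCNA2, differed by -0.76 with Qmimic (adjusted p = 0.13) and by -0.94 with Dmimic (adjusted p = 0.069), and FOXM1 by -0.95 with Dmimic (adjusted p = 0.0933).

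Of the 20 lists, camera called 11 with Qmimic (7 up, 4 down) and 8 with Dmimic (4 up, 4 down) with all 9 arrays, and 0 with an estimated correlation for either mimic. It called 7 and 4 without AllStar replicate 3, and 0 and 0 there with an estimated correlation (lowest adjusted p = 0.597 and adjusted p = 0.547). Apoptosis regulators had medians of 0.22 with Qmimic (adjusted p = 0.000342) and 0.26 with Dmimic (adjusted p = 6.6e-05), and 0.10 (adjusted p = 0.00797) and 0.11 (adjusted p = 0.00537) without AllStar replicate 3 (estimated correlation: adjusted p = 0.597 and adjusted p = 0.609). Cholesterol and fatty acid synthesis had medians of 0.23 (adjusted p = 0.000981) and 0.20 (adjusted p = 0.00833), and p53 targets 0.18 (adjusted p = 0.00473) and 0.20 (adjusted p = 0.0111). In these lists 0 members passed over all probe sets with all 9 arrays, and adjusted over the list alone 5 p53 targets rose with Qmimic, 3 rose with Dmimic and 0 members of the other two lists passed. Without AllStar replicate 3 the p53 targets PLK2 (1.55-fold, adjusted p = 0.0142) and TP53INP1 (1.58-fold, adjusted p = 0.0333) rose with Dmimic. With an estimated correlation the adjusted p = 0.643 for the 3 lists with Qmimic, and with Dmimic it was an adjusted p = 0.596 for apoptosis and cholesterol and adjusted p = 0.634 for p53 targets.

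Interferon response genes (median 0.18, adjusted p = 0.011), NF-kB and inflammatory cytokines (0.18, adjusted p = 0.019), integrated stress and unfolded protein response (0.18, adjusted p = 0.00633) and small RNA machinery (0.15, adjusted p = 0.0245) were called up with Qmimic with all 9 arrays. With an estimated correlation they had an adjusted p = 0.643, or adjusted p = 0.648 for small RNA machinery. Mesenchymal and invasion genes (0.13, adjusted p = 0.0143) were called up with Dmimic, with an adjusted p = 0.596 when the correlation was estimated. With the other mimic these lists had medians of 0.10, 0.08, 0.12, 0.15 and 0.09 in the same order, with adjusted p of 0.227, 0.0758, 0.0783, 0.0758 and 0.0651. Adjusted over the list alone, 3 interferon genes rose with Qmimic and 0 with Dmimic, 3 and 2 cytokine genes, 0 and 0 stress genes, 3 and 1 genes of small RNA machinery with 1 lower with Qmimic, and 1 and 3 mesenchymal genes. In the fit without AllStar replicate 3, SOD2 (1.56-fold, adjusted p = 0.0309) rose with Qmimic, TGFB2 (1.60-fold, adjusted p = 0.0127) rose and IFI44 (1.61-fold, adjusted p = 0.0218) fell with Dmimic. Members of the small RNA machinery went both ways there: DCP2 rose 1.73-fold with Qmimic and 1.81-fold with Dmimic, and CNOT6 fell 2.02-fold and 1.65-fold.

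Several of these calls at the preset correlation rested on 1 array. With an estimated correlation 0 of the 20 lists were called in any of the 9 fits that left out 1 array, with a lowest adjusted p of 0.580 for Qmimic and 0.547 for Dmimic. Without AllStar replicate 3 the calls ended for p53 targets (0.06, adjusted p = 0.107; with Dmimic 0.09, adjusted p = 0.251), and with Qmimic for interferon (0.07, adjusted p = 0.177), stress (0.06, adjusted p = 0.263) and small RNA machinery (0.01, adjusted p = 0.678). With Dmimic they ended for mesenchymal genes (0.05, adjusted p = 0.0514) and cholesterol synthesis (0.06, adjusted p = 0.144). The Qmimic call of cytokines ended without AllStar replicate 1 (0.20, adjusted p = 0.0531) and that of small RNA machinery without Qmimic replicate 2 (0.13, adjusted p = 0.058). New calls, which an estimated correlation did not give, appeared for mesenchymal genes with Qmimic without AllStar replicate 1 (0.14, adjusted p = 0.0477) or Qmimic replicate 3 (0.14, adjusted p = 0.0449), and for cytokines with Dmimic without Dmimic replicate 2 (0.11, adjusted p = 0.0189). With Dmimic, stress genes were called without AllStar replicate 1 (0.16, adjusted p = 0.0356) or 2 (0.17, adjusted p = 0.0308), and small RNA machinery without AllStar replicate 1 (0.23, adjusted p = 0.0101) or 2 (0.21, adjusted p = 0.0228), again at the preset correlation alone.

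Of 8 further lists 0 were called with all 9 arrays, and limma called 0 of their members there over all probe sets. Medians with Qmimic and Dmimic were -0.03 and -0.02 for receptor tyrosine kinases, 0.02 and 0.02 for epithelial genes, 0.08 and 0.09 for extracellular matrix and collagens, 0.10 and 0.11 for the WNT and NOTCH pathways, 0.07 and 0.05 for ribosomal proteins and 0.01 and 0.00 for glycolysis and hypoxia. The last list was called down with Qmimic without AllStar replicate 3 (-0.06, adjusted p = 0.0295; adjusted p = 0.597 with an estimated correlation). Adjusted over the list alone, 1 receptor tyrosine kinase rose with Qmimic, and 2 rose and 1 fell with Dmimic; 1 and 2 matrix genes rose; with Dmimic 2 WNT and NOTCH genes rose and 1 fell. The counts were 0 for epithelial genes, ribosomal proteins and glycolysis. Without AllStar replicate 3 ERBB3 rose 1.83-fold with Qmimic (adjusted p = 0.0202) and 1.68-fold with Dmimic (adjusted p = 0.0308), TIMP3 rose 1.53-fold with Qmimic (adjusted p = 0.03) and NDRG1 fell 1.53-fold with Dmimic (adjusted p = 0.0193). The lists whose median, mean and test differed in sign, such as receptor tyrosine kinases, were not called.

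Markers of other cell types did not rise as groups with either mimic. Leukocyte markers were called down with all 9 arrays, with medians of -0.17 with Qmimic (adjusted p = 0.011) and -0.12 with Dmimic (adjusted p = 0.0433), and an adjusted p = 0.643 and adjusted p = 0.596 with an estimated correlation. Their medians were -0.05 (adjusted p = 0.351) and 0.02 (adjusted p = 0.818) without AllStar replicate 3, and the Dmimic call also ended without Dmimic replicate 2 (-0.14, adjusted p = 0.0536). Fibroblast and endothelial markers had medians of -0.13 and -0.12 (adjusted p = 0.0811 and 0.131), and luminal breast epithelium markers, the last of these 8 lists, 0.01 and -0.12 (adjusted p = 0.619 and 0.8). Adjusted over the list alone, 1 luminal marker rose with each mimic, 1 fibroblast or endothelial marker rose with Dmimic and 0 leukocyte markers passed. CSF1R stands among the leukocyte markers and the reported targets, and ERBB3 among the luminal markers and the receptor tyrosine kinases.

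**Figure D3:**
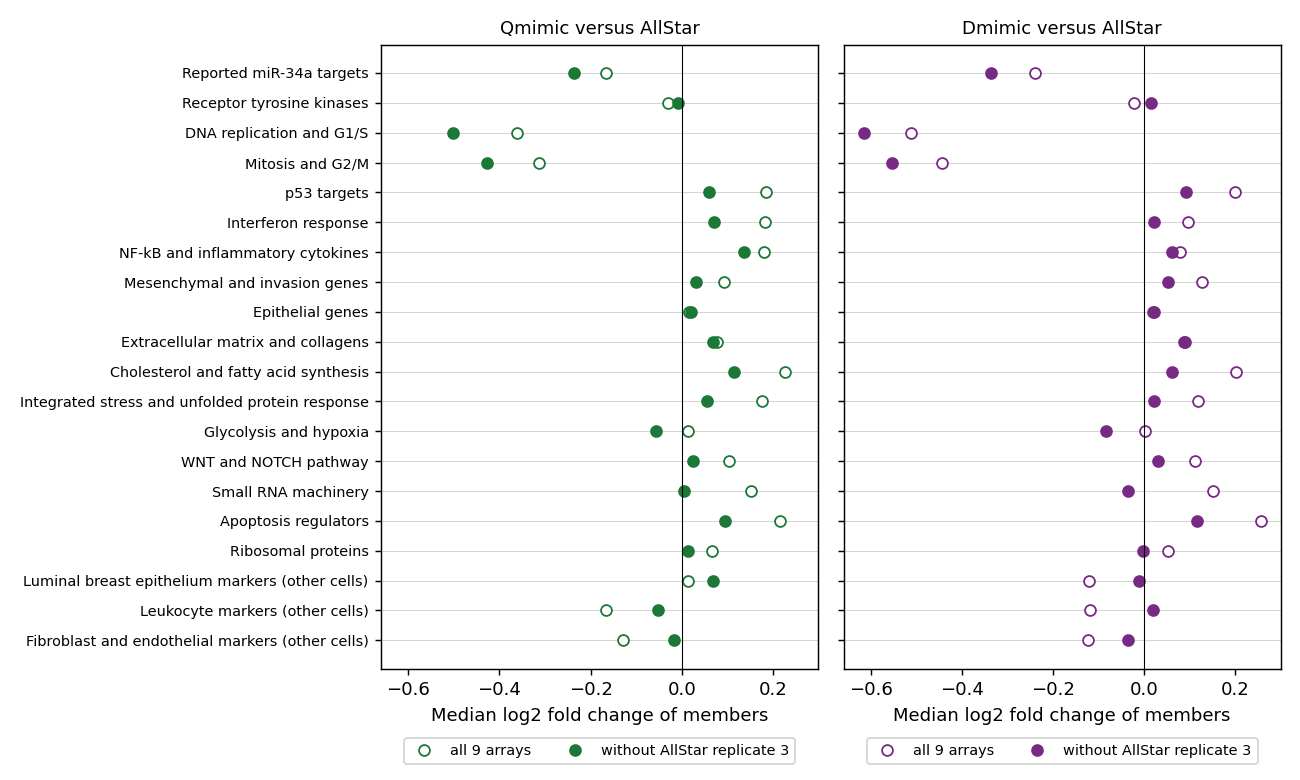
Median log2 fold change of the measured members of 20 gene lists, Qmimic versus AllStar on the left and Dmimic versus AllStar on the right, open points with all 9 arrays and filled points without AllStar replicate 3. The lists of reported targets, DNA replication and mitosis lie at -0.17, -0.36 and -0.31 with Qmimic and at -0.24, -0.51 and -0.44 with Dmimic with all 9 arrays.

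The comparison of Qmimic with Dmimic, at the same dose and time, asks whether the mimics differ. With all 9 arrays limma called 0 probe sets, with a smallest adjusted p of 0.0654. An unadjusted p under 0.05 was found for 1318, fewer than the 2730.65 expected by chance. Repeated quantile normalisation and cyclic loess of all 9 arrays each gave 0 higher and 15 lower with Qmimic, and a fit of the 6 mimic arrays alone 1 higher and 33 lower. Without AllStar replicate 3, which enters this comparison only through the estimate of the spread, 4 probe sets were higher and 40 lower with Qmimic than with Dmimic. FST, which encodes the activin-binding protein follistatin, was 1.90-fold lower with Qmimic (adjusted p = 0.00327, 3 of its 3 probe sets) and the chemokine CXCL8 1.87-fold lower (adjusted p = 0.00271, 2 of 2). BRWD1 (1.82-fold, adjusted p = 0.00202, 1 of 8 probe sets), the kinase GSK3B (1.78-fold, adjusted p = 0.00216, 2 of 5 probe sets) and NCBP2AS2 (1.75-fold, adjusted p = 0.00216) were lower as well. AGR2, a secretory pathway protein of epithelial cells, was 1.69-fold higher with Qmimic (adjusted p = 0.0359, 1 of 2 probe sets) and the cytokine IL7 1.54-fold higher (adjusted p = 0.0202).

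Chosen after their values were seen, RRAGD (2.90-fold lower with Qmimic, adjusted p = 0.000801), COL1A1 (2.53-fold and 2.21-fold lower on 2 probe sets) and the kinase MAPK9 (1.90-fold lower, adjusted p = 0.000706) fall outside the rule for named genes. For each of them the probe set with the highest mean, which represents the gene, was not called. Also chosen after their values were seen, the remaining 2 of the 4 probe sets higher with Qmimic were those of ID4 (1.57-fold, adjusted p = 0.0362) and PLEKHH1 (1.52-fold, adjusted p = 0.0362). Of the 40 lower probe sets, 20 were called lower with Qmimic against AllStar and were not called with Dmimic, 2 were called higher with Dmimic alone, and 18 were called with neither. The count of 44 was 24 without Qmimic replicate 1 as well and 32 to 50 without another mimic array.

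The camera test called 4 lists as higher with Qmimic than with Dmimic, with all 9 arrays and without AllStar replicate 3. These were DNA replication and G1/S (median difference 0.16, adjusted p = 7.6e-07), mitosis and G2/M (0.15, adjusted p = 1.92e-05), reported miR-34a targets (0.09, adjusted p = 6.98e-05) and interferon response (0.07, adjusted p = 0.0157). With an estimated correlation the adjusted p = 0.882 for replication genes and targets and adjusted p = 0.895 for the other two. Limma called 0 members of these lists over all probe sets, and 0 adjusted over the list alone, with all 9 arrays. Without Dmimic replicate 3 the difference was -0.02 (adjusted p = 0.829) for replication genes, -0.10 (adjusted p = 0.00101) for mitosis genes, which was the opposite direction, and 0.02 (adjusted p = 0.0673) for the targets. The mitosis call also ended without Qmimic replicate 3 (0.07, adjusted p = 0.0584), and that of interferon genes without Qmimic replicate 1 (0.04, adjusted p = 0.254) or Dmimic replicate 2 (0.02, adjusted p = 0.206).

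How far the changes with the 2 mimics overlap was compared across probe sets. In the fit without AllStar replicate 3, 98 probe sets rose with both mimics and 59 fell with both, and 0 went in opposite directions. Lists of the same sizes from simulated unchanged groups, which shared the 2 AllStar arrays, had a mean of 98.8 and 86.4 probe sets in common. The shared counts do not exceed these means, but such lists take the top of the ranking whether or not it passed the thresholds. At the thresholds themselves, the simulations shared at most 1 probe set in each direction. Unchanged groups give almost no calls there, so this was nearly fixed in advance and decides nothing. The overlap counts therefore do not separate an effect common to both mimics from the shared controls. Independent lists, a value that leaves out the shared controls, would have 0.701 and 0.573 in common. With all 9 arrays 0 were shared, since 0 passed with Qmimic (8924 at an unadjusted limma p under 0.05). Fold changes correlated across probe sets with r = 0.870 with all 9 arrays, against a mean of 0.849 and a maximum of 0.854 in simulations of unchanged groups that shared the controls. The r was 0.766 without AllStar replicate 3, against a simulated mean of 0.513 and a maximum of 0.530. In the upper part of the probe sets by mean level, the r with all 9 arrays lay within the simulations. It was 0.881, against a simulated mean of 0.880 and a maximum of 0.885. Without AllStar replicate 3 it was 0.806 there, against a mean of 0.451 and a maximum of 0.474. Over all probe sets the covariance of the fold changes was 0.0483 with all 9 arrays, where the shared controls alone gave 0.0259 in the simulations. Without AllStar replicate 3 it was 0.0239 against 0.00486. The differences, 0.0224 and 0.0191, are the part that the simulated noise of the shared controls leaves over. A difference in array quality between the mimic and AllStar arrays would also enter this part, and the 2 were not separated. The AllStar arrays are too few to be divided between the mimics. Probe sets are not independent replicates, and the simulations draw them as if they were. The count of 157 shared probe sets was 0 without AllStar replicate 1 as well, 5 without AllStar replicate 2, 43 without Qmimic replicate 1 and 41 without Qmimic replicate 2.

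**Figure D4:**
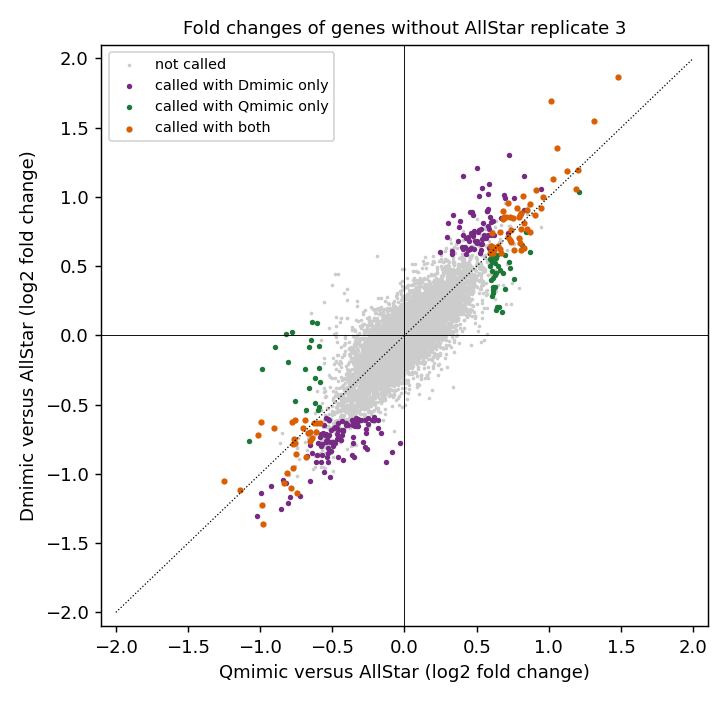
Log2 fold changes of 19775 genes against AllStar without AllStar replicate 3, Qmimic on the horizontal and Dmimic on the vertical axis, 1 point per gene. In orange, 52 genes rose and 29 fell with both mimics; 56 genes passed with Qmimic only (green), 170 with Dmimic only (purple), and the dotted line marks equal values.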

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

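The tests of a low yield, of other cells and of probe sets of like level on AllStar replicate 3, and that of RNA quality, were chosen only after the result was seen, as was the fit without that array; the other tests were written before their results. AllStar replicate 3 drew attention through control probe sets that no comparison uses: its 18S ribosomal RNA probe sets lay 3.27 above the mean of AllStar replicates 1 and 2 on the log2 scale, and its hybridisation spikes 0.835 above. Cells of another type stay open: of 3 marker lists none passed the 95th percentile of level-matched random lists, but all lay above the random median, the highest at the 75.2 percentile. A well given a mimic under the AllStar label was also tested: the array was nearer to AllStar replicates 1 and 2 for 98 of 98 probe sets higher with both mimics but for 30.5% of the 59 lower ones, which does not decide. Against probe sets of like level the 98 lay at -0.23 (19 of 98 above), where a mimic-treated well would lie above, which argues against that explanation, although the 59 lay at -0.12 (19 of 59 above), on the side it needs. A low yield of labelled message may account for the array, as high hybridisation spikes, high ribosomal RNA and low poly-A spikes are what it needs, but this remains a hypothesis found on the same data.

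Qmimic and Dmimic differed in 44 probe sets without AllStar replicate 3, by a direct test of the difference. A stronger action of one mimic on the genes that both change was not decided. Of the 44, 0% (0 of 44) were called the same way with both mimics, but that criterion could hardly be met. It needs a change of at least 1.5-fold with the weaker mimic and a further 1.5-fold with the other. Of the 44, 30 had opposite signs against AllStar. Among the 157 shared calls 97 were larger with Dmimic. The median ratio of their absolute log2 changes, Dmimic over Qmimic, was 1.04. A single deviating mimic array is argued against, as 24 to 34 of the 44 were called the same way when 1 of the 6 was left out, among 24 to 50 calls. Effects of each mimic on transcripts of its own could account for the difference and stay open, as the labels give no sequences, and so does RNA quality: the 3' minus 5' signal of ACTB was 0.093 higher with Qmimic, with every Qmimic array above every Dmimic array (exact p = 0.1, the smallest possible), while that of GAPDH differed by 0.0049 (exact p = 0.7). With all 9 arrays 0 probe sets differed by limma (1318 at an unadjusted p under 0.05, with 2730.65 expected by chance). After repeated quantile normalisation or cyclic loess 15 did, each time with 15 of 15 among the 44.

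Reported miR-34a targets differed between the mimics by a camera test of the difference, with a median of 0.086 (Qmimic minus Dmimic, log2), and by 0.02 (adjusted p = 0.0673) without Dmimic replicate 3. With an estimated correlation between genes that call did not hold (adjusted p = 0.882, and 0.688 without AllStar replicate 3).

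Other splits of the arrays were fitted in the same way. For both mimics against AllStar, as a comparison of 2 groups, the real split gave 251 probe sets and the highest other of 84 splits 1, and without AllStar replicate 3 the real split gave 320 and the highest other of 28 splits 1. In each, 1 split, the real one, gave as many, a share under 0.05. Every other split puts mimic and AllStar arrays in the same group, which widens the spread. These splits therefore do not exclude chance in the AllStar arrays, on which the counts rest. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05: Qmimic gave 0 (10 of 10 splits gave as many, highest other 0), Dmimic 3 (highest other 0), Qmimic against Dmimic 0 (highest other 0), and 44 without AllStar replicate 3 (highest other 0).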

How the results depend on the processing

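Array weights, the other AXL probe set and every alternative run on the fit without AllStar replicate 3 were chosen only after the result was seen, and the others were planned. Leaving out 1 array at a time gave 0 to 295 probe sets for Qmimic, 0 to 472 for Dmimic, 0 to 394 for both mimics, 0 to 44 for Qmimic against Dmimic and 0 to 157 shared by both mimics, and the highest value was without AllStar replicate 3 each time. AXL ranged from -0.80 to -0.55 with Qmimic and from -0.82 to -0.57 with Dmimic, the correlation of the mimics' changes from 0.766 to 0.922 (without AllStar replicate 1), and the lists called from 7 to 13, 4 to 10 and 3 to 5 for Qmimic, Dmimic and Qmimic against Dmimic. Starting without AllStar replicate 3 and leaving out a second array gave 2 to 486 for Qmimic, 1 to 902 for Dmimic, 0 to 631 for both, 24 to 50 for Qmimic against Dmimic and 0 to 226 shared. The lowest of these values but that of 24 were without AllStar replicate 1, where 1 AllStar array remains and is assumed to vary like the other groups. The cause of the changes below was not tested, apart from what a stricter or looser threshold does by construction.

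Signal over background can limit the lower part of the array, and its share in the counts was not tested. With all 9 arrays the upper part of probe sets by mean level gave 6 probe sets for Dmimic, 133 for both mimics, and 5 lists each for Qmimic and Dmimic. Repeated quantile normalisation gave 63, 103, 244 and 15 probe sets for Qmimic, Dmimic, both mimics and Qmimic against Dmimic, 25 shared, and 5 and 4 lists. Cyclic loess gave 129, 234, 374 and 15 probe sets, 73 shared, and 5 and 5 lists. Centring each array gave 0 for both mimics. A log2 change of at least 1.5 left 0 for Dmimic and 5 for both mimics, and a trend in eBayes gave 16 and 121. With only the arrays of the groups compared, there were 0 for Dmimic and 34 for Qmimic against Dmimic. The estimate of array weights stopped with a warning about convergence. AllStar replicates 1, 2 and 3 had weights of 0.896, 5.17 and 0.057, and the mimic arrays 0.775 to 1.62. The weighted control thus rested mostly on AllStar replicate 2. Array weights gave 594, 696, 546 and 58 probe sets, 323 shared, 6 and 5 lists and a correlation of 0.794. AXL then lay at -0.56 (adjusted p = 0.0011) with Qmimic and -0.56 (adjusted p = 0.00155) with Dmimic. The adjusted p of AXL over its alternatives ranged from 0.0011 to 0.593 with Qmimic and from 0.00155 to 0.564 with Dmimic. Camera with an estimated correlation called 0 lists for Qmimic, 0 for Dmimic and 0 for Qmimic against Dmimic.

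Without AllStar replicate 3, a log2 change of at least 1.5 left 4, 6, 4 and 1 probe sets for Qmimic, Dmimic, both mimics and Qmimic against Dmimic, and adjusted p alone gave 953, 1261, 1648 and 117, with 428 shared. Only the arrays of the groups compared gave 480 for Qmimic and 13 for Dmimic. The replicate numbers did not pair the arrays, and a block for them changed the counts: with all 9 arrays it gave 1 for Qmimic, 0 for Dmimic and 1 for both mimics, and without AllStar replicate 3 it gave 104, 17 and 91, with 10 shared.

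Of 1007 values of named genes under the alternatives, 0 called values turned in sign, 235 were no longer called, and 8 uncalled ones, all of BCL2, changed sign. Of 1080 list values, 83 lost their call, 25 gained one, and 33 uncalled ones changed direction. Of the called lists 2 turned, both for Qmimic against Dmimic without Dmimic replicate 3: DNA replication and G1/S to -0.021 and mitosis and G2/M to -0.10. Leaving out 1 array at a time, their values ranged from -0.021 to 0.29 and from -0.10 to 0.30, with the highest of each without Dmimic replicate 2. The lists of reported targets, replication and mitosis kept their direction and their call against AllStar, with each mimic, under each alternative but the estimated correlation. Alternatives for miR-34a seed sites were not run.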

Other observations

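The test of the mimic arrays' quality, the cilium list itself and the fit without AllStar replicate 3 were chosen only after the result was seen. Genes of cilia, the antenna-like organelles of the cell surface, had positive medians with both mimics, but with an estimated correlation between genes p = 0.173 with Qmimic and p = 0.106 with Dmimic with all 9 arrays, and p = 0.162 and p = 0.0979 without AllStar replicate 3. Among the 98 measured genes of a cilium list, which left out the cilium genes first noticed to rise, 65 were positive with Qmimic and 70 with Dmimic without AllStar replicate 3, with median log2 changes of 0.11 and 0.14 and with 1 and 5 members called. The medians were 0.19 and 0.23 with all 9 arrays, and limma called 0 members. KIF3A, a motor subunit of the transport along cilia, rose by 0.69 with Qmimic (adjusted p = 0.0106) and 0.86 with Dmimic (adjusted p = 0.00625) without AllStar replicate 3. With Dmimic the transport genes IFT81 (0.73, adjusted p = 0.0237), IFT22 (0.74, adjusted p = 0.0255) and IFT88 (0.91, adjusted p = 0.0378) and the chaperonin-like BBS12 (0.72, adjusted p = 0.0355) rose too. KIF3A had been among the calls over both mimics seen before the list was written, and without it the medians were 0.11 and 0.13.

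As a hypothesis, genes of cilia may rise as a group with both mimics: the list's median stood at the 100 percentile of 10000 level-matched random lists with each mimic. The camera p without AllStar replicate 3 was 1.98e-05 with Qmimic and 1.24e-07 with Dmimic at the preset correlation, and p = 0.162 and p = 0.0979 with an estimated one. The narrow range of AllStar replicate 3 is argued against as the whole cause, since the lower of the medians was 0.115 without that array. Array quality stays open: the mimic arrays had hybridisation spikes on average 0.308 above AllStar replicates 1 and 2, though those of Dmimic replicate 1 were not above AllStar replicate 1. The list's 0.48 percentile in AllStar replicate 3, where the spikes were higher still, comes from 1 array with faults the mimic arrays lack. Chance in AllStar replicates 1 and 2, which both comparisons share, stays open too, and no biological explanation was tested.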
